A study of Mus musculus with 4 samples.

How the data were processed

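Cultured epidermal keratinocytes of mice that carried K5-Cre and a loxP-flanked Casp8 allele, over a null allele (F/-) or a wild-type allele (F/+), were compared on 4 two-colour Agilent mouse arrays. Casp8 encodes caspase-8, the initiator protease of death receptor signalling, and K5-Cre is a recombinase expressed from the keratin 5 promoter, which is active in basal keratinocytes. Per the labels' protocols, the epidermis was separated with Dispase, cells were dissociated with trypsin, grown in serum-free keratinocyte medium with pituitary extract and epidermal growth factor, and passaged by trypsin; total RNA was amplified to cRNA and labelled. The series' design text states that keratinocytes came from 2 mice of each genotype and that RNA was taken at passage 1, the early passage, and passage 3, the late passage, which makes 8 RNA samples. Each array held the F/- RNA of a pair in Cy3 and the F/+ RNA of that pair in Cy5, and there were 2 arrays per passage. Titles, descriptions and the passage entry of channel 2 place the Cy5 RNA of both late arrays at passage 3, while its source name gives the first passage; the former, which are more numerous, were followed.

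No array had the dyes exchanged. A dye effect therefore adds to the genotype ratio of every array and cannot be removed from it; it cancels, where it is equal on all arrays, in the difference between passages. All 4 arrays lay on 1 slide and were read in 1 scan, so slide and scan do not separate the groups and no fit with slide as a block could be made.

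The deposited scanner files were made with Agilent Feature Extraction 9.1.3.1, per the submitters' processing notes. Per the file headers they hold, for each spot, raw intensity as mean signal and median local background in both channels, the intensity processed by the scanner software with spatial detrending, multiplicative detrending and linear and lowess dye normalization, and the log10 ratio of Cy5 over Cy3 of the processed intensities. The authors' value table, deposited with the series, holds log10 ratios that equal this column with the sign turned (Cy3 over Cy5, largest gap 4.96e-06), so scale, centring and direction are known; its medians were -0.00223, 0, 0 and -0.000733 on the early arrays of pairs 1 and 2 and the late arrays of pairs 1 and 2. It leaves 1896, 1130, 2350 and 1774 spots empty on these arrays, by a rule not given in the sources used here.

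From the raw intensities, background was corrected with normexp (offset 50) and ratios were normalized within each array by loess in limma 3.58.1 (R 4.3.3), with control spots and spots flagged as outliers at weight 0. Ratios are log2 of Cy3 over Cy5, that is F/- over F/+, the direction of the authors' table. Of 45018 spots, 43379 were gene spots, 1486 positive and 153 negative controls. Spots of one probe were averaged, and 35574 of 41174 probes were kept that were well above background in at least 1 channel on at least 2 arrays, with at most 1 missing array. Between 75.8% and 85.4% of gene spots were well above background in Cy3, between 80.6% and 87.9% in Cy5, and no spot was saturated. The number of arrays, 2 per passage, limits the precision. Median raw signal lay between 101 and 139 in Cy3 and between 166 and 253 in Cy5, over local backgrounds of 37 to 39 and 59 to 61. Probes were named through the accession in the file (21702), the symbol (5446) or a unique older symbol (2592) with a RefSeq gene table of assembly GRCm38.p6; 5834 kept the name in the file. No genome build applies to the arrays, and no coordinates are given.

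Genotype was tested with limma's moderated test on all 4 arrays with passage as the group, which gives the ratio at each passage, the mean of both, and late minus early; p-values were adjusted with the Benjamini-Hochberg method and called at 0.05. All tests were two-sided. The fit had 2 residual degrees of freedom per probe and 2.81 from the prior. The change with passage within each genotype was tested with limma's separate-channel fit after loess and Aquantile normalization, with a correlation of 0.742 between the channels of a spot. F/- and F/+ values share arrays, so array effects enter both passage comparisons. The same animals were sampled at both passages, so the pair numbers pair the arrays; deviations of same-numbered arrays from their passage mean correlated at -0.000464 across probes. The pairing as a block was an alternative. Arrays of 1 pair at 2 passages are not independent animals, and the mean over 4 arrays treats them as if they were.

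A total of 23 gene lists with 556 entries, of which 538 were measured, were fixed before the data were examined, as were the design, the rule for named genes and all alternatives. The lists cover keratinocyte states, death, interferon, NF-kB, cytokine, wound, matrix and metabolic genes, markers of other skin cells and sex-linked genes. The mesenchymal list also holds the epithelial genes Cdh1, Epcam, Ocln and Esrp1, so its median is not that of mesenchymal genes alone. Each gene was represented by its brightest probe. Each list was compared with the rest of 23999 genes and unnamed transcripts using camera with a preset correlation of 0.01, and fry was run as well. Camera was run again with an estimated correlation, a form that refers its statistic to the 2 residual degrees of freedom of the fit. With so few, hardly any list could be called, so a call lost in that form cannot be laid to correlation alone. Where the estimated correlation was high, the loss cannot be laid to the few degrees of freedom alone either. List p-values were adjusted over the 23 lists of a comparison. Genes named for each passage are the 10 largest in each direction past the threshold with the same sign in both arrays; where fewer passed, they were filled with genes at least 2-fold changed in the same direction in both arrays, ranked by the smaller ratio, and are given as values that did not pass. The mean, the difference and the passage comparisons name the first 5 in each direction past the threshold, with the same sign in all arrays or pairs compared. Casp8 and the sex-linked genes are given always, and from each list the 4 members with the smallest p at the late passage and up to 6 past the threshold could be named; 2 genes that these rules name are not reported here. A gene with several probes is named by the probe with the largest change. Fold changes of probes near background are compressed by the offset.

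The tests were checked on simulated ratios of 35574 probes. A changed probe had the same shift on every array it affected, with independent noise, so the recovery does not cover shifts that vary between animals. With 100 probes changed by a log2 ratio of 1 and 100 by 2, the mean test recovered 84% and 99%, with 10 false calls. The early test recovered 70% and 97%, with 6, and the late test 72% and 97%, with 8. The separate-channel test of F/- recovered 13% and 79%, with 5 false calls. The list test called the 1 list that was moved and 0 others. Genes were simulated as independent, while the correlation estimated in the data reached 0.76 for interferon genes, so this does not check the test on correlated genes. Alternatives changed the background correction, offset, dye normalization, signal source, probe filter, flagged spots, pairing, fold threshold, channel normalization, channel correlation and probe choice, and left out each array in turn.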

Results

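Gene expression was measured in primary epidermal keratinocytes of F/- mice, whose Casp8 genotype pairs a loxP-flanked allele with a null allele in the presence of K5-Cre, and of F/+ mice with the same Cre and a wild-type allele beside the flanked one. Each of the 4 arrays compared 1 F/- with 1 F/+ culture, with 2 arrays at culture passage 1 (early) and 2 at passage 3 (late). Values are log2 ratios of F/- over F/+, given as mean ± SD over arrays. The series title names change over culture time, so the genotypes were compared at each passage, over both, and between passages.

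The Casp8 probe read higher in the RNA labelled F/- on 3 of 4 arrays and lower on 1. Its log2 ratios were 0.42 and 0.18 on the early arrays and 0.47 and -0.20 on the late arrays of pairs 1 and 2. The deleted part of the gene and the position of the probe are not given in the sources used here, so this probe checks neither the deletion nor the labels, and F/- and F/+ stand for RNA labelled so. Among sex-linked genes, Eif2s3y on the Y chromosome had log2 ratios of -1.27 and -0.29 at the early and -1.28 and -0.27 at the late passage in pairs 1 and 2. Eif2s3y was well above background in both channels on 4 arrays. The Xist probe with the largest ratios read -0.17 and -0.69 early and -0.21 and -0.64 late. It was well above background in Cy3 on 0 arrays and in Cy5 on 2, so these ratios lie near background in both channels. A second Xist probe, well above background in both channels on 4 arrays, read -0.087 and 0.091 early and -0.061 and -0.12 late. The third, also dim in Cy3, read between -0.33 and 0.076. Probes of Ddx3y, Kdm5d, Uty and Tsix read between -0.32 and 0.19 on the 4 arrays. Across 35475 probes, which are not independent replicates, ratios of any pair of arrays correlated with Pearson's r between 0.477 and 0.581 and Spearman's rho between 0.429 and 0.533.

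At the early passage, Mmp13, Mmp9 and Ccl6 read higher and Spink5 and Lgals7 lower in F/- cultures. The collagenase gene Mmp13 had a log2 ratio of 3.11 ± 1.23 (SD, n = 2), the gelatinase gene Mmp9 2.17 ± 0.78, the chemokine gene Ccl6 1.98 ± 0.31, Pdpn, which encodes podoplanin, 1.64 ± 0.25, and Calcb 1.59 ± 0.070. The collagen gene Col5a3 stood at 1.67 ± 0.28 and the actin-binding gene Cttn at 1.60 ± 0.064. Lower readings were those of Spink5, which encodes a protease inhibitor of the epidermis, at -2.14 ± 0.53, Lgals7 at -1.87 ± 0.30, Krtdap at -1.75 ± 0.45, and Lor, which encodes the cornified envelope protein loricrin, at -1.57 ± 0.13. Also lower were Cstdc6 at -1.70 ± 0.42, Smpd3 at -1.49 ± 0.22, Sh3rf2 at -1.31 ± 0.040, Sema3c at -1.27 ± 0.014, Lce1a2 at -1.23 ± 0.033 and Rpl37a at -1.21 ± 0.011. Cox17 and Klf2 read 1.97 ± 0.50 and 1.88 ± 0.39, but a second probe of Cox17 read -0.22 and one of Klf2 0.17. Other probes of Col5a3 and Sema3c read -0.26 and -0.15.

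None of these genes passed limma's test at the early passage, in which 0 of 35574 probes had an adjusted p under 0.05 (smallest 0.0704) and 7333 an unadjusted p under 0.05, against 1779 by chance. With a background offset of 0 in place of 50, 69 probes passed, 49 higher and 20 lower. In both early arrays 97 probes were past 2-fold in one direction, 64 higher and 33 lower, while 5 were so in opposite directions; median centring in place of loess gave 37 higher and 139 lower.

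Gene lists moved at the early passage without any member past the threshold over all probes. Suprabasal and cornified envelope genes were lower (median -0.53 over 42 genes, 3 of them positive, camera adjusted p = 3.23e-11), 19 of them when adjusted over the list alone. Interferon-stimulated genes were higher (median 0.71, 41 of 41 positive as the mean of the 2 arrays, camera adjusted p = 1.52e-10). Irf7 stood at 1.52 ± 1.20 and Ifi35 at 0.81 ± 0.48, and 1 gene passed when adjusted over the list alone. On the array of pair 1 the interferon median was 1.22, with 40 of 41 positive. On that of pair 2 it was 0.16, with 26 of 41 positive. NF-kB feedback and target genes were higher (median 0.37, adjusted p = 4.48e-06), 9 of 22 when adjusted over the list alone, with Tnfaip3, which encodes the NF-kB inhibitor A20, at 0.84 ± 0.25. MHC genes (median 0.47, adjusted p = 1.28e-04), protease, growth factor and wound genes (median 0.34, adjusted p = 0.00366), cytokines and chemokines (0.41, 0.0196) and basal keratinocyte genes (0.31, 0.0498) were higher. So were death receptor and apoptosis genes (median 0.13, adjusted p = 0.0196) and the markers of fibroblasts (0.16, 0.0196) and leukocytes (0.33, 0.0267). With an estimated correlation the adjusted p of these lists lay between 0.604 and 0.747, and no list was called. That form uses 2 residual degrees of freedom, and correlation alone does not explain the loss. For NF-kB genes the estimate was 0.00045, below the preset 0.01, yet the unadjusted camera p went from 5.85e-07 to 0.0318. For interferon genes the estimate was 0.76, and the unadjusted camera p went from 1.32e-11 to 0.289. That is a larger loss at the same degrees of freedom, so correlation weighed on this call. Estimates were 0.61 for leukocyte, 0.45 for MHC, 0.43 for fibroblast, 0.36 for basal, 0.26 for suprabasal and 0.10 for protease and wound genes. They lay below 0 for cytokine and death receptor genes. Fry called 0 of 23 lists (smallest adjusted p = 0.0509), with 4 at an unadjusted p under 0.05.

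Single arrays and the normalization weighed on the early lists. Without the early array of pair 1, the median was 0.16 for interferon and 0.18 for MHC genes, and the calls ended of basal (median 0.073, adjusted p = 0.623), protease and wound (0.064, 0.116), leukocyte (0.064, 0.872), fibroblast (0.13, 0.217), death receptor (0.12, 0.141) and cytokine genes (0.28, 0.0680). Without the early array of pair 2, medians were -0.88 for suprabasal, 1.22 for interferon, 0.72 for MHC, 0.52 for basal, 0.58 for leukocyte, 0.25 for fibroblast and 0.26 for cytokine genes. With median centring they were -0.97 for suprabasal, 0.033 for NF-kB, 0.21 for MHC, 0.24 for cytokine, 0.21 for leukocyte, -0.16 for basal and -0.046 for protease and wound genes, and 0.021 for death receptor genes (adjusted p = 0.281), whose call ended, as did that of basal genes (adjusted p = 0.393). Without background subtraction the basal call ended as well (adjusted p = 0.0706), and with the mean of all probes per gene its median was 0.18. The fibroblast median was 0.33 with the scanner's ratios.

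**Figure D1:**
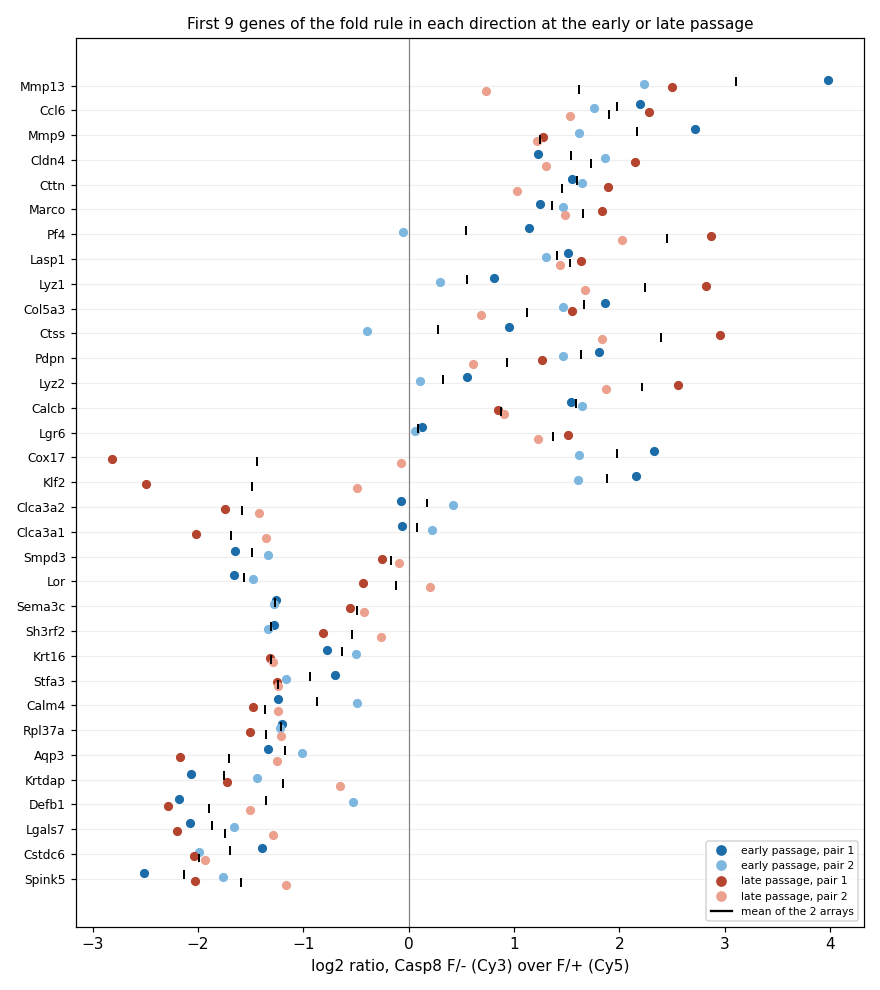
Log2 ratios of F/- over F/+ (x axis) for the first 9 genes of the fold rule in each direction at the early or late passage (y axis), with 1 point per array and a black bar at the mean of the arrays of a passage. Mmp13, Ccl6 and Mmp9 lie above 0 and Spink5, Cstdc6 and Lgals7 below 0 on all 4 arrays, while Cox17 and Klf2 lie above 0 on the early and below 0 on the late arrays.

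At the late passage, Pf4, Ctss, Lyz1 and Lyz2 read higher and Cstdc6 and Defb1 lower in F/- cultures. The chemokine gene Pf4 had a log2 ratio of 2.45 ± 0.60 (SD, n = 2), the lysosomal protease gene Ctss 2.40 ± 0.79, the lysozyme genes Lyz1 and Lyz2 2.25 ± 0.81 and 2.21 ± 0.49, Ccl6 1.90 ± 0.53 and the scavenger receptor gene Marco 1.66 ± 0.24. The tight junction gene Cldn4 stood at 1.73 ± 0.60, Lasp1 at 1.53 ± 0.15, Lgr6 at 1.37 ± 0.20 and Mmp9 at 1.25 ± 0.047. Lower readings were found for Cstdc6 at -1.99 ± 0.072, Defb1, which encodes a beta-defensin, at -1.90 ± 0.55, Lgals7 at -1.74 ± 0.64, Aqp3, which encodes a water and glycerol channel, at -1.71 ± 0.65, and the stress keratin gene Krt16 at -1.31 ± 0.019. Clca3a1 and Clca3a2 stood at -1.69 ± 0.48 and -1.58 ± 0.23, Calm4 at -1.36 ± 0.17, Rpl37a at -1.36 ± 0.20 and Stfa3 at -1.24 ± 0.0051. A second probe of Lyz2 read 0.67, and other probes of Lasp1 read between -0.24 and 0.70.

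None of these genes passed limma's test at the late passage either, in which 0 of 35574 probes had an adjusted p under 0.05 (smallest 0.0790) and 7109 an unadjusted p under 0.05. In both late arrays 58 probes were past 2-fold in one direction, 31 higher and 27 lower, and 1 in opposite directions; median centring gave 11 higher and 184 lower.

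Cell cycle genes stood lowest among the lists at the late passage. All 38 members read lower in F/- cultures (median -0.53, camera adjusted p = 9.87e-18, and 0.480 as adjusted p with an estimated correlation), 31 of them when adjusted over the list alone. Ccna2 and Ccnb1, which encode cyclins A2 and B1, read -1.02 ± 0.26 and -0.83 ± 0.084, Ccnb2 -0.91 ± 0.21 and the spindle checkpoint gene Bub1 -0.82 ± 0.0037. Suprabasal genes (median -0.21, adjusted p = 6.72e-05), stress keratins and alarmins (-0.17, 0.0113) and hypoxia and glycolysis genes (-0.15, 0.0157) were lower too. Fibroblast markers were higher (median 0.72 over 22 genes, adjusted p = 2.57e-06, and 0.37 as median with the mean of all probes per gene), with Mmp2 at 1.08 ± 0.39 and Col5a2 at 1.06 ± 0.48, as were mesenchymal genes (median 0.57, adjusted p = 1.71e-05), 10 of 23 when adjusted over the list alone, with Fn1, which encodes fibronectin, at 1.47 ± 0.44. NF-kB genes were higher (median 0.36, adjusted p = 6.91e-05), 11 of 22 when adjusted over the list alone. Interferon-stimulated genes (median 0.30, adjusted p = 2.38e-04), leukocyte markers (0.28, 6.12e-04), protease and wound genes (0.27, 0.00120), cholesterol biosynthesis (0.078, 0.0435) and MHC genes (0.25, 0.0439) were higher. With an estimated correlation the adjusted p of these lists lay between 0.480 and 0.574. No list was called in that form, which had 2 residual degrees of freedom. Fry called 0 of 23 lists (smallest adjusted p = 0.0710), with 6 at an unadjusted p under 0.05.

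Among the late lists, 4 calls ended without the late array of pair 2: interferon (median 0.19, adjusted p = 0.0777), MHC (0.10, 0.446), stress keratin (-0.10, 0.0777) and cholesterol genes (0.059, 0.380), the last also without either early array (0.0672 for each) and with the pair as a block (0.0785). The hypoxia median was -0.25 without the late array of pair 2. Without the late array of pair 1, medians were 0.30 for fibroblast, 0.31 for mesenchymal, 0.11 for leukocyte, -0.12 for suprabasal, -0.32 for stress keratin and 0.12 for cholesterol genes. With median centring they were -0.87 for cell cycle, -0.71 for stress keratin, -0.40 for hypoxia, -0.34 for suprabasal, 0.18 for mesenchymal, 0.071 for interferon, 0.079 for protease and wound, -0.34 for cholesterol and -0.086 for MHC genes, and 0.12 for NF-kB genes, and the calls of cholesterol (adjusted p = 0.183), MHC (0.817) and NF-kB genes (0.0618) ended. With the scanner's ratios the calls of MHC (median 0.38, adjusted p = 0.0720), hypoxia (-0.18, 0.0720) and stress keratin genes (-0.11, 0.107) ended, though the MHC and hypoxia medians lay further from 0. In the same ratios the medians of leukocyte, suprabasal and cholesterol genes were 0.59, -0.41 and 0.17. With the mean of all probes per gene the cholesterol median was 0.14, and without background subtraction the calls of cholesterol (adjusted p = 0.0506) and MHC genes (0.101) ended.

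**Figure D2:**
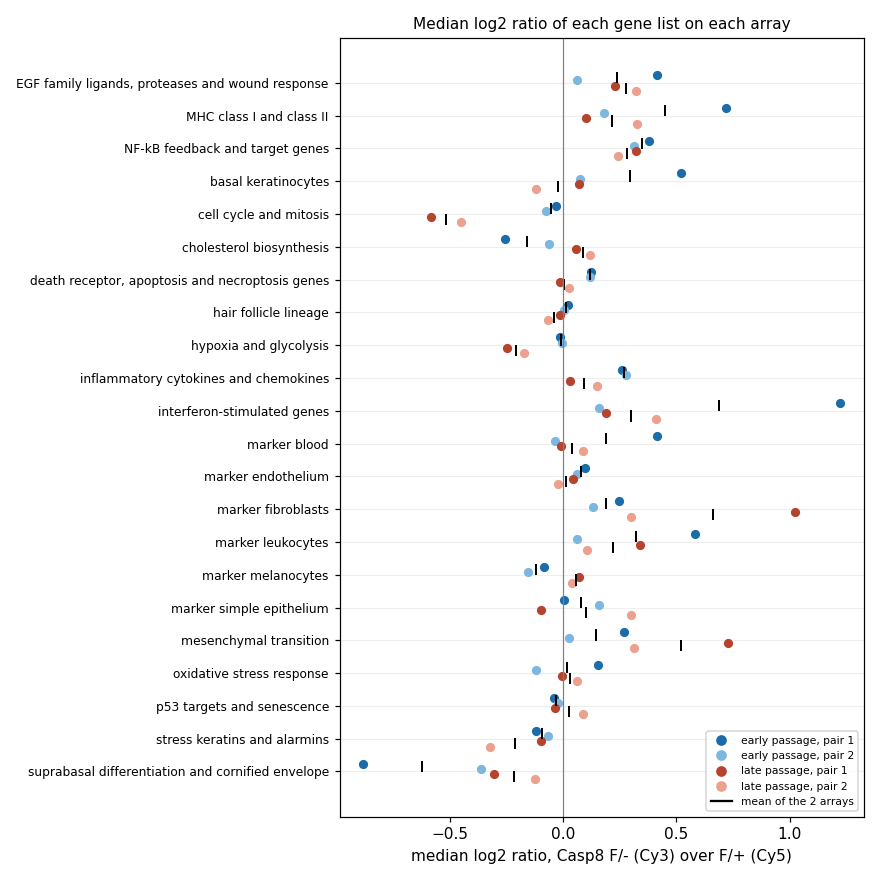
Median log2 ratio of F/- over F/+ (x axis) over the measured members of each gene list (y axis), with 1 point per array and a black bar at the mean of the arrays of a passage; the sex-linked list is left out. The cell cycle median lies at -0.58 and -0.45 on the late arrays and at -0.030 and -0.076 on the early arrays.

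Averaged over both passages, Mmp13, Mmp8, Mmp9 and Ccl6 rose and Spink5, Lgals7 and Krtdap fell in F/- cultures. The cells were not sorted, so the cell type behind these readings was not tested. Mmp13 rose by a log2 ratio of 2.36 ± 1.33 (SD, n = 4, limma adjusted p = 0.0396), Ccl6 by 1.94 ± 0.36 (adjusted p = 0.0257), Mmp8 by 1.80 ± 0.89 (adjusted p = 0.0461), Mmp9 by 1.71 ± 0.70 and Cldn4 by 1.64 ± 0.44 (adjusted p = 0.0257 for both). Spink5 changed by -1.86 ± 0.56, Cstdc6 by -1.84 ± 0.30 and Lgals7 by -1.81 ± 0.42 (adjusted p = 0.0257 for each). Defb1 changed by -1.65 ± 0.83 (adjusted p = 0.0459) and Krtdap by -1.47 ± 0.60 (adjusted p = 0.0300). Each of these 10 genes had the same sign on 4 of 4 arrays, which the naming rule required. In all, 3144 of 35574 probes passed, 2080 higher and 1064 lower, which name 2501 genes, and 71 were past 2-fold higher and 36 past 2-fold lower. The count treats the 4 arrays as separate animals: 0 probes passed when the arrays of each pair were averaged first (smallest adjusted p = 0.0513), and 0 passed without the early array of pair 1, the early array of pair 2 or the late array of pair 1. The 10 genes above lost the threshold in each of these 3 cases, and Mmp8 and Defb1 also without background subtraction. Median centring gave 917 higher and 3050 lower probes, the scanner's ratios gave 1934 probes, and dye and genotype cannot be separated in this comparison.

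Suprabasal, stress keratin and cell cycle lists were lower in this average. Of 42 suprabasal and cornified envelope genes 13 fell and 0 rose, or 24 and 1 when adjusted over the list alone (median -0.53, camera adjusted p = 9.51e-10), with Sbsn at -1.19 ± 0.36, Calm4 at -1.11 ± 0.43 and Dmkn at -1.07 ± 0.34. Of 25 stress keratins and alarmins 8 fell, with Stfa3 at -1.09 ± 0.26, Krt16 at -0.97 ± 0.40 and Krt17 at -0.78 ± 0.19, and 1 rose, S100a7a at 0.94 ± 0.15 (median -0.15, adjusted p = 0.0415). Of 24 basal keratinocyte genes 5 fell, among them the basal keratin genes Krt14 at -0.66 ± 0.25 and Krt5 at -0.60 ± 0.29, and 3 rose, with Bcam at 0.78 ± 0.36, and the list was not called (median 0.17, adjusted p = 0.269). Of 38 cell cycle genes 7 fell, or 21 when adjusted over the list alone, where 1 rose, with Cdc20 at -0.75 ± 0.36 (median -0.27, adjusted p = 2.88e-08). The adjusted p of suprabasal, stress keratin and cell cycle genes was 0.481 for each with an estimated correlation. The stress keratin call ended without the early array of pair 2 (median -0.061, adjusted p = 0.194), without the late array of pair 2 (-0.10, 0.0788) and with the scanner's ratios (-0.21, 0.280), and with median centring the medians of cell cycle and stress keratin genes were -0.57 and -0.58.

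NF-kB, interferon, MHC and death receptor lists were higher in the same average. Of 22 NF-kB genes 8 rose, or 12 when adjusted over the list alone, with Tnfaip3 at 0.84 ± 0.26, Tnip1 at 0.68 ± 0.11 and Relb at 0.57 ± 0.070 (median 0.35, camera adjusted p = 6.25e-06). Of 26 cytokine and chemokine genes 6 rose, with Tnf at 0.97 ± 0.44, Il23a at 0.86 ± 0.19 and Ccl2 at 0.86 ± 0.58, and 2 fell, among them Il33 at -1.13 ± 0.27 (median 0.19, not called, adjusted p = 0.0603). Of 41 interferon-stimulated genes 1 rose, Irf1 at 0.45 ± 0.36, and all were positive as the mean of both passages (median 0.48, camera adjusted p = 2.89e-09). Of 19 MHC genes 4 rose, with Tap2 at 0.67 ± 0.30 and Tapbp at 0.64 ± 0.12 (median 0.36, adjusted p = 0.00176). Of 35 death receptor, apoptosis and necroptosis genes 2 rose, among them the caspase gene Casp6 at 0.40 ± 0.17, or 1 when adjusted over the list alone (median 0.077, adjusted p = 0.0415). With an estimated correlation the adjusted p of the NF-kB, interferon, MHC and death receptor lists was 0.481, 0.554, 0.570 and 0.481. Without the early array of pair 1 the medians of interferon, MHC and death receptor genes were 0.24, 0.24 and 0.031, and without that of pair 2 the interferon median was 0.77 and the death receptor median 0.12. The death receptor call ended without the early array of pair 1 (adjusted p = 0.128), without the late array of pair 1 (median 0.051, adjusted p = 0.0797), with the scanner's ratios (0.0653) and with median centring (median -0.086, 0.797). Median centring also ended the MHC call (median 0.017, adjusted p = 0.0700) and gave medians of 0.073 for NF-kB and 0.29 for interferon genes.

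Protease and wound, mesenchymal, fibroblast and leukocyte lists were higher as well. Of 31 protease, growth factor and wound genes 5 rose, with Pdgfb at 1.32 ± 0.31 and Mmp2 at 1.17 ± 0.35, and 1 fell, Epgn, which encodes the EGF family ligand epigen, at -1.05 ± 0.16 (median 0.29, camera adjusted p = 6.36e-04, and -0.036 as median with median centring). Of 23 genes of the mesenchymal list 5 rose, among them the epithelial gene Epcam (median 0.36, camera adjusted p = 6.42e-04). Fn1 stood at 1.22 ± 0.40 and Acta2, which encodes smooth muscle actin, at 0.84 ± 0.49. However, 3 other probes of Acta2 read between -0.17 and 0.054 and 1 other probe of Fn1 0.14. Of 22 fibroblast markers 3 rose, with Col5a2 at 0.79 ± 0.42 (median 0.40, adjusted p = 3.78e-05). Of 23 leukocyte markers 3 rose, Lyz1 at 1.40 ± 1.10, Lyz2 at 1.27 ± 1.14 and the complement gene C1qa at 1.06 ± 0.53 (median 0.35, adjusted p = 9.51e-04). The adjusted p of these 4 lists lay between 0.481 and 0.622 with an estimated correlation. Of all 23 lists fry called 0 in this average (smallest adjusted p = 0.0507), with 8 at an unadjusted p under 0.05. The fibroblast median was 0.23 with the mean of all probes per gene and 0.65 with the scanner's ratios, with which the mesenchymal median was 0.56. Without 1 array the fibroblast median lay between 0.21 and 0.65, lowest without the late array of pair 1 and highest without that of pair 2, and the leukocyte median between 0.17 and 0.52, lowest without the early array of pair 1 and highest without that of pair 2. Without the early array of pair 1 the fibroblast median was 0.24, and without the late array of pair 1 the leukocyte median was 0.23.

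Other lists were not called in this average. Of 22 hypoxia and glycolysis genes 5 fell, with Ldha and Pdk1, genes of lactate production and pyruvate use, at -0.78 ± 0.35 and -0.78 ± 0.20, and 1 rose, Ndrg1 at 0.47 ± 0.17, or 9 and 4 when adjusted over the list alone (list median -0.083, camera adjusted p = 0.265). Cholesterol biosynthesis had a median of -0.024 (adjusted p = 0.757), oxidative stress 0.061 (0.305), p53 targets and senescence -0.017 (0.691) and hair follicle genes -0.028 (0.912). Markers of blood had a median of 0.047 (adjusted p = 0.136), endothelium 0.029 (0.265), melanocytes -0.027 (0.969), simple epithelium 0.053 (0.474) and sex-linked genes -0.034 (0.442). For cholesterol, p53 and melanocyte genes the median was negative while the test pointed upwards.

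Between passages, the genotype ratio of cell cycle genes differed while no single probe did. Limma called 0 of 35574 probes for late minus early (smallest adjusted p = 0.819), with 2074 at an unadjusted p under 0.05 against 1779 by chance. The cell cycle list was lower late than early by a median of -0.53, with 0 of 38 members positive (camera adjusted p = 3.96e-24), 5 of them when adjusted over the list alone. Cholesterol biosynthesis genes were higher by 0.29 (adjusted p = 1.59e-05), 4 of 21 when adjusted over the list alone, where 1 was lower, and Insig1, a regulator of sterol synthesis, read -0.18 ± 0.23 early and 0.96 ± 0.23 late. Hypoxia and glycolysis genes were lower by -0.21 (adjusted p = 0.00214). The adjusted p of these 3 lists was 0.493 for each with an estimated correlation, and fry called 0 of 23 lists (smallest adjusted p = 0.127), with 4 at an unadjusted p under 0.05. Their calls held without any single array, with medians of 0.17 for cholesterol genes without the early array of pair 1 and -0.12 for hypoxia genes without the late array of pair 1.

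A further 7 lists differed between passages, and leaving out single arrays turned their medians or ended their calls. Interferon genes (median -0.38, adjusted p = 9.65e-04) turned to 0.19 without the early array of pair 1 (adjusted p = 8.88e-04), and were -1.04 without that of pair 2 and -0.23 without the late array of pair 1. Mesenchymal genes (median 0.35, adjusted p = 0.00123) were not called without the late array of pair 1 (median 0.19, adjusted p = 0.209). Fibroblast markers (median 0.17, adjusted p = 0.0125) were not called without that array (median -0.0054, adjusted p = 0.923) or, with a median as large, without the early array of pair 2 (median 0.17, adjusted p = 0.164). The calls of basal (median -0.31, adjusted p = 0.00163), suprabasal (0.12, 0.00163), MHC (-0.22, 0.0125) and cytokine genes (-0.16, 0.0383) ended without the early array of pair 1, with medians of -0.11, 0.021, 0.043 and -0.15 and adjusted p of 0.278, 0.546, 0.562 and 0.0956. The basal call ended also without the late array of pair 2 (median -0.20, adjusted p = 0.248), the suprabasal call without that array (median -0.031, adjusted p = 0.396) and with the scanner's ratios (median 0.032, adjusted p = 0.0866), and the MHC call without the late array of pair 1 (median -0.14, adjusted p = 0.314). The cytokine call ended also without the late array of pair 1 (median -0.26, adjusted p = 0.0608), without that of pair 2 (median -0.23, adjusted p = 0.0792) and with the mean of all probes per gene (adjusted p = 0.0628), while its median without 1 array lay between -0.31 and -0.15. Without the early array of pair 2 the medians of basal, suprabasal, MHC and cytokine genes were -0.56, 0.28, -0.54 and -0.31. The suprabasal median was 0.29 without the late array of pair 1, and the MHC and fibroblast medians were -0.34 and 0.47 without that of pair 2. With median centring the suprabasal and cytokine medians were 0.30 and -0.28, and the cytokine median was -0.37 with the scanner's ratios. With an estimated correlation the adjusted p of these 7 lists lay between 0.590 and 0.680.

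From passage 1 to passage 3, Lce3c, Lce3f, Cnfn and Defb14 fell and Clu, Plekhs1, Cnn1 and Fn1 rose in both genotypes. In F/+ cultures the late cornified envelope genes Lce3c and Lce3f changed by -7.38 ± 0.66 (SE, n = 2 per passage, limma adjusted p = 0.00168) and -6.49 ± 0.67 on the log2 scale, Cnfn by -6.76 ± 0.31, Krtdap by -5.98 ± 0.44 and the defensin gene Defb14 by -5.94 ± 0.51. Clu rose by 5.92 ± 0.48, Plekhs1 by 5.77 ± 0.72, Cnn1, which encodes calponin, by 5.05 ± 0.36, Acta2 by 4.63 ± 0.23 and Fn1 by 4.48 ± 0.35. In F/- cultures Lce3c changed by -7.99 ± 0.66 (limma adjusted p = 0.00133), Lce3f by -7.10 ± 0.67, Cnfn by -6.91 ± 0.31, Defb14 by -6.87 ± 0.51 and Degs2 by -6.29 ± 0.41, while Clu rose by 5.83 ± 0.48, Plekhs1 by 5.48 ± 0.72, Cnn1 by 5.34 ± 0.36, Fn1 by 4.99 ± 0.35 and Acta2 by 4.79 ± 0.22. The Acta2 values come from different probes in the 2 genotypes, and its brightest probe changed by 0.96 in F/+ and 0.22 in F/- without passing.

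Members of the lists moved with passage. Of 42 suprabasal genes 28 fell in F/+ and 25 in F/-, and 0 rose in either; adjusted over the list alone 32 and 30 fell and 1 rose in each. Of 38 cell cycle genes 6 fell in F/- and 0 in F/+. Of 23 leukocyte markers 6 fell in F/+ and 4 in F/-, and of 14 melanocyte markers 5 and 6. Of 23 genes of the mesenchymal list 5 rose in each genotype, and of 22 fibroblast markers 3 rose and 0 fell in each. Cytokine and chemokine genes went both ways, with 7 higher and 7 lower of 26 in F/+ and 5 and 7 in F/-, as did stress keratins and alarmins, with 3 higher and 6 lower of 25 in F/+ and 3 and 7 in F/-. In F/+ cultures 2008 of 35475 probes passed limma's test, 1188 higher and 820 lower at the late passage, and in F/- cultures 1808 passed, 1058 higher and 750 lower. Both shared 838 probes that rose and 566 that fell, against 35.4 and 17.3 for independent lists, and 0 moved in opposite directions, though the comparisons share arrays. The difference of the passage changes, tested in the same fit, called 0 probes, with 2482 at an unadjusted p under 0.05 against 1774 by chance.

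With the pair as a block, 4144 probes passed in F/+ and 3859 in F/-. Without the early array of pair 1 the counts were 177 and 97, without the early array of pair 2 211 and 144, and without the late array of pair 1 4648 and 3108. Fn1 and Defb14 lost the threshold in both genotypes without either early array, as did Cnn1 and Degs2 in F/-, and Cnn1 in F/+ lost it without the early array of pair 2. Among the probes that passed, 57 rose and 120 fell in F/+ and 25 rose and 72 fell in F/- without the early array of pair 1, and 54 rose and 157 fell in F/+ and 38 rose and 106 fell in F/- without that of pair 2, so the balance turned. Scaling of the processed signal turned it too, with 598 higher and 1308 lower probes in F/+ and 523 and 1179 in F/-.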

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

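Of the tests in this part, that of probes of the same gene was set before its result was seen, and the tests of dye bias shared by all probes of a gene, sign patterns, cell shares, a deviating late array and equal dye bias were chosen after. Groups held 2 arrays each, too few to compare the gap between 1 array and the others with the range of its group.

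Lists whose genotype ratio differed between passages in the camera test of late minus early were cell cycle (median -0.53), cholesterol biosynthesis (0.29), interferon-stimulated (-0.38), mesenchymal (0.35), basal keratinocyte (-0.31), suprabasal (0.12), hypoxia and glycolysis (-0.21), fibroblast marker (0.17), MHC (-0.22) and cytokine genes (-0.16). None of these differences was called with an estimated correlation (smallest adjusted p = 0.493), a form of camera with 2 residual degrees of freedom. The named genes Cox17 (-3.42) and Klf2 (-3.38) had positive ratios on both early and negative ratios on both late arrays, and limma's test of the difference gave an adjusted p of 0.819 for each.

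The first pattern is the 3144 probes past the threshold for the genotype difference averaged over both passages. Another probe of the same gene shared the sign of the called probe in 69.0% of 1675 genes. In 100 random re-pairings the share was 53.9% on average and at most 56.6%. This argues against dye bias that differs from probe to probe as the whole cause. In the remaining genes the other probe did not share the sign, so such bias stays open for part of the probes. Dye bias shared by all probes of a gene cannot be told apart from genotype, since 0 arrays had the dyes exchanged. The 8 sign patterns of the arrays are too few for a share under 0.05, and the real pattern, 1 of the 8, gave 3144 probes while the highest other gave 0. The genotype stays among the open explanations, as untested.

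The second pattern is the higher reading of leukocyte genes in late F/- cultures. Of 5 leukocyte markers with a mean log2 level of at least 9, 80% were higher on both late arrays (Lyz1, Lyz2, Fcer1g and Thy1, the last also a fibroblast marker), while Cd68 read -0.24 and 0.085, so a larger share of leukocytes may be a source and was neither excluded nor shown. Their median lay above that of 7 melanocyte markers by at least 0.28 on each late array. This gap is less than the leukocyte median differed between the late arrays. On each late array the leukocyte median was the value of Thy1, so the gap rests on a gene shared with the fibroblast list. Among the genes higher on both late arrays, Fcer1g read lowest, below Thy1, Lyz1 and Lyz2. A lower share of keratinocytes therefore stays open too. Lyz2 reached 2.56 and 1.87, while the abundant melanocyte genes Pmel and Mlana read -0.69 and -0.22, and -0.61 and -0.16. On each late array, though, 5 of the 7 melanocyte markers were positive, among them the most abundant, Dct, at 0.049 and 0.16. Without the cut on level, 16 of 23 leukocyte markers were positive on the late array of pair 1 and 18 on that of pair 2. Of 14 melanocyte markers 9 were positive on each late array. No step of the culture protocol sorted the cells, and an effect of genotype within keratinocytes was not tested.

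The third pattern is the lower reading of cell cycle genes in late F/- cultures. The list median was -0.58 and -0.45 on the late arrays, the value nearest 0 being -0.45, which argues against 1 deviating late array as the cause. The difference late minus early, in which a dye effect equal on every array cancels, had medians of -0.62 and -0.39 in pairs 1 and 2, which argues against such dye bias. Slower division of late F/- cells is a candidate explanation, as a hypothesis, and culture density and the share of other cells were not tested. A count of dividing keratinocytes of both genotypes at passage 3, at equal density, would test it.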

How the results depend on the processing

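All alternatives were chosen before the data were examined. The probes changed with genotype at the early passage, at the late passage and in late minus early numbered 0 under each alternative run, except 69 at the early passage with an offset of 0. For the mean of both passages, 3144 became 1934 with the scanner's log ratios, 1818 with the authors' value table, 0 with arrays averaged within each pair, and between 0 and 3966 without 1 array; with the pair as a block it was 3228. Probes past 2-fold in both arrays, 97 early and 58 late, numbered 176 and 195 with median centring, 217 and 297 with the scanner's ratios, 848 and 730 at 1.5-fold, and 7 and 7 at 3-fold. Called lists, 10 early, 12 late, 11 for the mean and 10 for late minus early, fell to 0 in each comparison with an estimated correlation. That form had 2 residual degrees of freedom and could hardly call any list. Without 1 array they numbered between 5 and 13 early, 8 and 13 late, 10 and 13 for the mean, and 6 and 11 for late minus early. Passage counts were 4144 in F/+ and 3859 in F/- with the pair as a block, between 177 and 4648 and between 97 and 3108 without 1 array, and 2717 in F/- with independent channels. Median centring turned the medians of basal (-0.16) and protease and wound genes (-0.046) early, cholesterol (-0.34) and MHC genes (-0.086) late, and death receptor (-0.086) and protease and wound genes (-0.036) in the mean. Camera still called the protease and wound list with median centring, early (adjusted p = 0.0453) and in the mean (adjusted p = 0.0353). For late minus early, medians without 1 array lay between -1.04 and 0.19 for interferon, -0.54 and 0.043 for MHC, -0.0054 and 0.47 for fibroblast, and -0.031 and 0.29 for suprabasal genes. Leaving out an array leaves 1 at a passage, assumed to vary like the others, and averaging leaves fewer values; other causes were not tested. Of 70 named results 0 changed sign in the alternatives run for them, and 16, 17, 10 and 0 lost the threshold without the early arrays of pairs 1 and 2 and the late arrays of pairs 1 and 2, and 2 without background subtraction. The naming rule required the same sign in the arrays compared, so leaving out an array could not turn a named genotype ratio. Named results of the early and late passage had not passed the threshold and could not lose it. Only those of the mean and of the passage change in each genotype could, with 5 genes per direction each. A slide block was not run, since there was 1 slide. Signal near background limits the ratios of dim probes.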

Other observations

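Genes of the p53 and oxidative stress lists, which were not called as lists, include members past the threshold in the mean of both passages. Mdm2, a p53 target, rose by 0.45 ± 0.14 (SD, n = 4, limma adjusted p = 0.0359), and Gstm2, a glutathione transferase gene, changed by -0.76 ± 0.30 (limma adjusted p = 0.0262). Lmnb1, which encodes lamin B1, read -1.59 ± 0.87 and missed the threshold (limma adjusted p = 0.0536). From the early to the late passage Lyz2 changed by -3.06 in F/+ (adjusted p = 0.00405) and had a value of -1.18 in F/- (adjusted p = 0.112). The difference between these passage changes was not called, with 0 probes past the threshold. The melanocyte genes Pmel and Mlana changed by -2.26 and -2.04 in F/+ and by -2.58 and -2.08 in F/-. Of 8 simple epithelium markers 2 rose with passage in F/- and 3 in F/+, where 1 fell, Krt20 at -0.94 (adjusted p = 0.0461).

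The source name of the late Cy5 RNA gives the first passage, against the other labels, and the test of it was chosen after related values were seen. If that RNA came from passage 1, the Cy5 channel would change little between the early and late arrays. With each channel normalized by itself, over the 1808 probes changed with passage in Cy3, the median Cy5 change in the direction of Cy3 was 1.28 in pair 1 (quartiles 0.86 and 1.94) and 1.46 in pair 2 (quartiles 1.00 and 2.13), against 1.32 and 1.34 in Cy3. The smaller ratio of Cy5 over Cy3 was 0.970, which argues against passage 1 as the origin of the late Cy5 RNA in either pair. The exact passage and the genotype of that RNA were not tested.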
